A study of Mus musculus with 4 samples.

How the data were processed

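RNA was measured in whole retinas of mice at postnatal day 10, on a mixed background that contains at least C57BL6 and 129. Per the labels' protocols, all mice received 20 ug of 4HT, the active form of tamoxifen, by intraperitoneal injection at postnatal day 3. RNA of 3 batches per genotype was pooled before library preparation with the TruSeq RNA Sample Prep Kit v2, and each batch held 4 to 8 retinas of 2 to 4 mice. The labels do not state whether strand was kept.

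The authors deposited 1 table with an FPKM, a lower and an upper interval bound and a status per gene and library. TopHat, Cuffdiff and the mm10 build are named in the submitters' processing notes. Their versions, the gene annotation, the read length, the read totals and the level of the intervals are not given in the sources used here. FPKM, as deposited by the authors, are fragments scaled to transcript length and library size, so they are relative within a library and a change in abundant RNA shifts all others. How fragments were divided among near-identical or overlapping genes is not given in the sources used here, so such genes are treated as uncertain. A total of 4285 genes share their deposited locus with another gene.

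Columns were assigned to libraries by the number in the column name, which is the number in the description of a single sample. Groups were taken from the labels. No column of per-sample values lay outside the series.

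Log2 ratios were computed on FPKM plus a pseudocount of 0.5, so changes of low genes are understated. Genes entered with a mean of at least 1 FPKM over the 4 libraries and a status of OK in each. A total of 145 genes had another status in at least 1 library. This left 13150 genes, of which 249 were short RNA genes. Each comparison sets 1 library against 1, so no comparison has a spread within its groups and none was tested. A fit of both factors without their interaction over the 4 libraries would leave 1 residual degree of freedom, and was not run. Genes at least 2-fold apart were counted, and members of lists at least 1.5-fold apart. Whether the deposited intervals of a pair of libraries overlap was recorded as a description. When libraries were drawn, the distance from a value to its upper bound was read as 2 SD, which is an assumption.

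The 5 comparisons, the 26 gene lists, the rule for named genes and all alternative settings except those named below as chosen later were fixed before the data were examined. A list median was set beside 10000 random lists of the same size, matched on mean expression in 20 bins, and called apart outside the central 95%. Genes of a real list vary together, unlike random ones, so the percentile describes these libraries and is not a test. The lens list had 1 tested member, Crybb3, and the list for fibroblasts and the ocular surface 2, Col1a2 and Mgp, so neither has a median. The rule named, per comparison, the 8 genes of highest and of lowest ratio without short RNA genes and provisional symbols (Gm followed by a digit, or ending in Rik), up to 4 members per direction from 8 vascular, pathway, hypoxia and gliosis lists, up to 3 from every other list, and 15 genes set in advance. Short RNA genes were also recognised from reference annotation for that rule. The text names a part of those genes, and a few of them are not reported here. Cd93, Eltd1, Klhl33, Nid1, Prnd, Serpina3h, Txnip, Vwa1, Gm14440, Cbx7, Spp1 and Slc39a8 fall outside the rule and were named after their values were seen.

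Coordinates, transcript length and GC content came from GENCODE M21, which uses the same mm10 assembly. A single reference gene overlapping the deposited locus was found for 22553 of 23278 genes, and 98.4% of tested genes had a transcript length. Settings tried as planned were pseudocounts of 0.1 and 1, minimum means of 0.5 and 5 FPKM and none, re-centring on the median, rescaling to the same total (TPM), all statuses, intervals that do not overlap, 1.5-fold and lists without their largest member. Leaving out short RNA genes, leaving out genes on X and Y and removing a robust cubic trend on transcript length and GC content were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

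Relative depth was read from the deposited intervals. A squared ratio of the value to its SD was computed for each gene, and its commonest value among low genes was taken as the worth of 1 fragment in that library. Between 49.1% and 51.0% of low values lay within 0.02 of a whole multiple, so the depths are approximate and no counts were recovered.

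The procedure was tested on simulated libraries drawn from gamma distributions. The mean of each gene was that of the pair of libraries compared, and each library kept its own ratio of SD to value. A gene low in either library of a pair thus kept its large relative SD at a higher mean, which widened its draws. In the simulation of the stabilized library against WT, over 13150 genes, 0% of 50 genes changed 1.5-fold, 36% of those changed 2-fold and 94% of those changed 3-fold passed the 2-fold limit. Of 24 unchanged lists 1 was called apart there, and in the simulation of the stabilized knockout against the knockout 4 of 24 were. All 24 lists shifted by 0.5 were called in each of the 5 simulations. Unchanged pairs were drawn 100 times per comparison. Without regard to the intervals they gave as many or more 2-fold calls as the observed libraries in most comparisons. Outside short RNA genes the observed lower calls of every comparison lay below the lowest draw. The draws were therefore noisier than the libraries, and their totals are a loose reference. The count of unchanged calls with intervals apart was added after those totals had been seen, as were the counts of calls shared by unchanged draws of disjoint contrasts.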

Results

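Whole retinas of mice at postnatal day 10 were profiled by RNA sequencing in 4 genotypes, with 1 library per genotype. The genotypes cross the state of Ndp, the gene of the secreted ligand Norrin, with the state of beta-catenin in endothelial cells. Norrin acts through the receptor Frizzled-4 (Fzd4) and beta-catenin in the growing retinal vasculature. The WT library had neither change, and the knockout library lacked Ndp. The stabilized library carried the Ctnnb1flex3 allele, which recombination turns into a stabilized beta-catenin, together with Pdgfb-CreER, a tamoxifen-activated recombinase expressed in endothelial cells. The stabilized knockout library combined all of these. Each library was made from RNA of 3 batches, each of 4 to 8 retinas from 2 to 4 mice, and pooling removed any measure of the spread between mice. No single comparison below therefore has a replicate check, and no p-value was computed. Stabilization and loss of Ndp were each measured in a second pair of libraries on the other background. The intervals given are those deposited for each FPKM, and their level is not given in the sources used here. They describe the estimate within a library and not the variation between animals.

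The deposited table held 23278 genes, of which 13150 had a mean of at least 1 FPKM and a usable status in every library. The deposited FPKM summed to 423695 in WT, 417911 in the knockout, 405525 in the stabilized library and 427109 in the stabilized knockout. Total read counts are not given in the sources used here. An estimate from the width of the deposited intervals of low genes placed the depth of the knockout at 0.536, of the stabilized library at 0.426 and of the stabilized knockout at 0.577 of that of WT. By this approximate estimate WT was the deepest library and the stabilized library the shallowest.

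Ndp (X chromosome, 16885521 to 16911774 on the minus strand, GENCODE M21 on mm10) was measured at 2.98 FPKM in WT (deposited interval 2.17 to 3.80) and 2.35 FPKM in the stabilized library (1.68 to 3.02). It was 0.873 FPKM in the knockout (0.561 to 1.19) and 0.869 FPKM in the stabilized knockout (0.557 to 1.18). Both libraries labelled as Ndp knockouts thus had about 0.29 times the WT value, with intervals apart from that of WT. The table has a single value per gene, so the part of the transcript that remained cannot be read from it. Ctnnb1 (chromosome 9, 120929216 to 120960507), the beta-catenin gene, lay at 144, 138, 156 and 161 FPKM in WT, knockout, stabilized and stabilized knockout, with overlapping intervals. Pdgfb, whose regulatory sequence drives the CreER, was at 1.14 and 1.11 FPKM in WT and knockout and at 2.57 and 2.92 FPKM in the libraries with CreER. It lies on chromosome 15 (79995874 to 80014977), close to Apobec3 and Cbx7, which were higher in the same libraries.

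The sex-linked genes differed along with the Ndp genotype. Xist, the non-coding RNA of the inactive X chromosome, was at 135 and 130 FPKM in WT and the stabilized library and at 1.25 and 1.28 FPKM in the knockout and stabilized knockout. The Y-linked gene Ddx3y was at 18.7 and 20.1 FPKM in the knockout and stabilized knockout and below 0.2 FPKM in the other libraries. Both Ndp knockout pools therefore had the expression of males and both pools with intact Ndp that of females, so every contrast of Ndp genotype is also a contrast of sex.

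**Figure D1:**
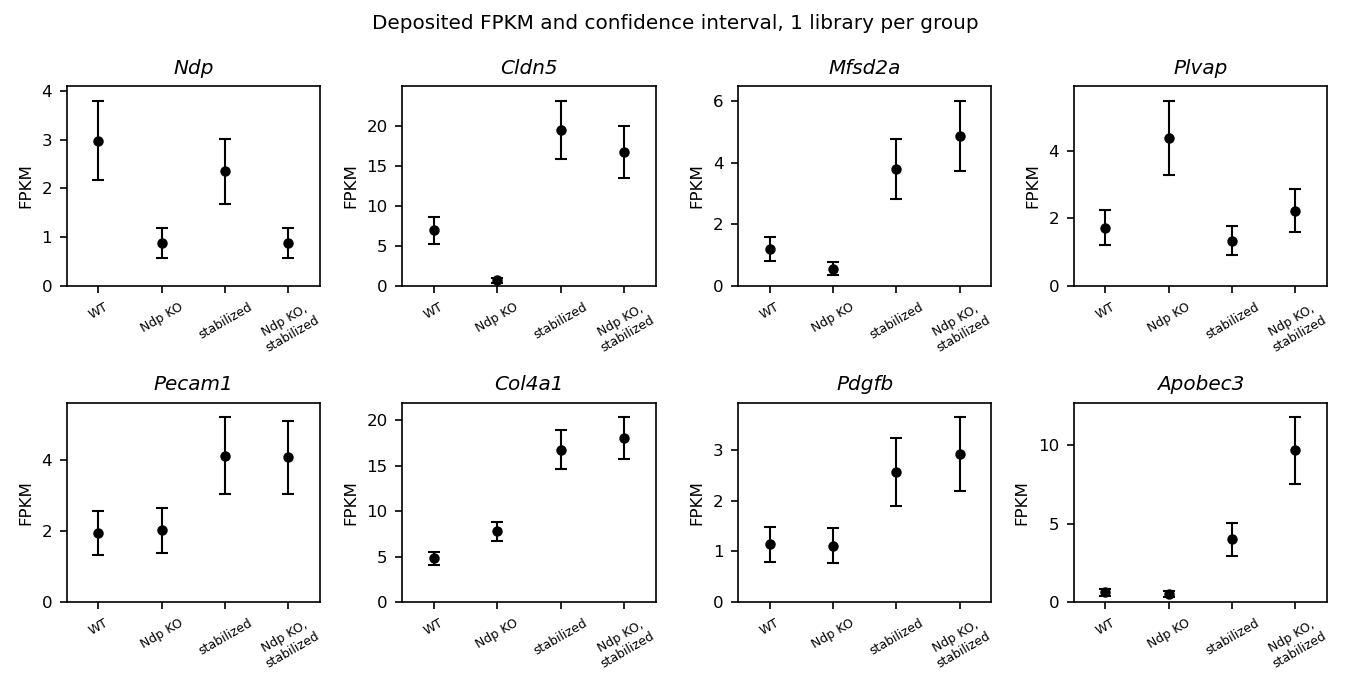
Deposited FPKM (linear vertical axis starting at 0) of 8 genes in the 4 libraries; points are the single library of each group and bars its deposited interval. Cldn5 went from 6.91 FPKM in WT to 0.675 FPKM in the Ndp knockout and was 19.4 and 16.7 FPKM in the libraries with stabilized beta-catenin.

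The knockout against WT addresses the loss of Norrin with unmodified beta-catenin. The clearest difference among endothelial genes was in Cldn5 (chromosome 16, 18776847 to 18778262), which encodes the tight junction protein claudin-5. It was at 0.675 FPKM in the knockout (0.378 to 0.971) and 6.91 FPKM in WT (5.18 to 8.63), a log2 ratio of -2.66. Other transporters of the blood-retina barrier were lower as well. Mfsd2a, a lysophospholipid transporter, had a log2 ratio of -0.70, the amino acid transporter Slc38a5 -0.73 and the thyroid hormone transporter Slco1c1 -0.78. Plvap, the diaphragm protein of fenestrated endothelium, was higher, at 4.40 FPKM (3.30 to 5.50) against 1.72 FPKM (1.20 to 2.24), a log2 ratio of 1.14.

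Of the 16 tested barrier genes, 4 were at least 1.5-fold lower in the knockout, none was 1.5-fold higher and 12 lay between. The list median was -0.25, below the central 95% of 10000 random lists matched on expression (-0.10 to 0.06). With a pseudocount of 1 in place of 0.5, Slco1c1, Slc38a5 and Mfsd2a fell short of 1.5-fold (log2 ratios of -0.45, -0.46 and -0.51). Slco1c1 and Slc38a5 were below 1 FPKM in WT and Mfsd2a was at 1.20 FPKM, and the intervals of all of these were apart. A pseudocount of 1 understates falls from values this low, so that setting says little of their size. Slco1c1 was so low in WT that its complete absence from the knockout would not have reached 1.5-fold there. Abcb1a, the P-glycoprotein gene, and Sox17, an endothelial transcription factor, were below the minimum mean for a call, at 0.287 and 0.399 FPKM in WT and 0.0665 and 0.126 FPKM in the knockout. The 16 pan-endothelial genes had a median of 0.04, inside the random range of -0.11 to 0.08, and no member was 1.5-fold apart. Pecam1 was at 2.02 FPKM against 1.93 FPKM with overlapping intervals. Cdh5 was at 1.36 FPKM against 0.754 FPKM with intervals apart, 1.80 times as high by the deposited values and just short of 1.5-fold with the pseudocount (0.57). In the list of fenestrated and tip-cell genes 5 of 14 members were 1.5-fold higher and the median was 0.19. These were Plvap, Igfbp3 (0.87), Col4a1 (0.64), Col4a2 (0.63) and Adm (0.60). With a pseudocount of 1, Col4a2 (0.57) and Adm (0.52) fell short of 1.5-fold. Arterial and venous genes had a median of -0.00. The 8 mural cell genes had a median of 0.15, although the pericyte gene Rgs5 was lower at -0.84. That median lay inside the random range with a minimum of 0.5 FPKM (0.02), with no filter (0.01) and after correction for transcript length and GC content (0.09).

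Among the other lists, Norrin/Fz4 pathway components had a median of -0.03 with Ndp as the 1 member beyond 1.5-fold. Of 21 canonical Wnt targets and feedback genes only 8 were expressed enough to be tested. Their median was -0.12 at percentile 3.34 of the random lists, with no member beyond 1.5-fold. It lay below the random range in 6 of the alternatives, at -0.17 with a pseudocount of 0.1 and -0.14 after the correction for length and GC content. Axin2 was at 5.30 FPKM in the knockout and 5.37 FPKM in WT, and Lef1 was below 1 FPKM in all 4 libraries. Genes of the stress response of Muller glia, the main glia of the retina, had a median of 0.13, with A2m (0.67) and the intermediate filament gene Gfap (0.61) highest, though neither reached 1.5-fold with a pseudocount of 1 (0.50 and 0.56). The median of 29 hypoxia genes was 0.04, at the edge of the random range. Hk2 (0.64) exceeded 1.5-fold beside Adm, whose intervals overlapped, and Vegfa was at 116 FPKM against 107 FPKM with overlapping intervals. Rod genes had a median of 0.17, led by the transducin gene Gnat1 (401 against 239 FPKM), and ganglion cell genes 0.23. Microglia genes had a median of -0.16, with Cd68 at -0.66 and its intervals overlapping. Muller glia markers (0.06), astrocytes (0.10), cones (0.05), bipolar (0.00), amacrine (-0.01) and horizontal cells (-0.04), proliferation (-0.00) and the interferon response (0.14) lay inside their random ranges. Immediate early genes (0.12) and genes of the retinal pigment epithelium (0.10), an adjoining tissue, lay just above theirs, but not after the correction for length and GC content for the former (0.07) or with a minimum of 0.5 FPKM for the latter (0.05). The erythroid median was -0.10, inside its range, and the sex-linked median 3.98.

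In all, 59 genes were at least 2-fold higher and 106 at least 2-fold lower in the knockout than in WT. Of these, 48 and 86 were short RNA genes such as microRNAs and snoRNAs, which leaves 11 higher and 20 lower genes. The 5 highest of the remainder were the unnamed LOC100861570, listed at 0 in WT, and the Y-linked Eif2s3y, Ddx3y, Uty and Kdm5d. Xist (-6.27), Hba-a2 (-3.10) and Cldn5 (-2.66) were among the lowest. Hba-a2 has a near-identical copy, Hba-a1, so the separate value of each is uncertain here and below. Unchanged pairs of libraries, drawn from the deposited intervals, gave on average 113.4 higher and 114.5 lower calls, and 46.2 and 48.9 outside short RNA genes. The totals of this contrast do not exceed those of unchanged pairs, but that reference cannot judge them. Its lowest draws outside short RNA genes held 30 higher and 38 lower calls, more than were observed. The draws were therefore noisier than these libraries. Outside short RNA genes 9 higher and 14 lower genes had intervals apart, against 1.0 and 2.6 in unchanged pairs.

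The stabilized library against WT addresses activation of beta-catenin in endothelial cells with Ndp intact. Genes of blood vessels were higher across several lists fixed beforehand. Cldn5 reached 19.4 FPKM (15.8 to 23.1) against 6.91 FPKM, a log2 ratio of 1.43. Slco1c1 had the highest ratio in the barrier list, at 3.63 FPKM against 0.396 FPKM (2.20). Slc38a5 (1.48) and Mfsd2a (1.34) were higher too. Col4a1, a collagen of vascular basement membranes, was at 16.7 FPKM against 4.81 FPKM (1.70), and Acta2, the smooth muscle actin, at 1.53 FPKM against 0.392 FPKM (1.19).

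Of the 16 pan-endothelial genes 6 were 1.5-fold higher and none lower, with a median of 0.51 outside the random range of -0.14 to 0.13. Cdh5 (1.39), Eng (1.38), Tie1 (1.21) and Sox18 (1.10) led the list, and Pecam1 was at 4.12 FPKM against 1.93 FPKM. Of 16 barrier genes 8 were 1.5-fold higher (median 0.56). This call rested on members of low expression. With a minimum of 5 FPKM the median was -0.05, inside the random range, on fewer members. That minimum leaves out Slco1c1 and Mfsd2a and keeps Cldn5. Fenestrated and tip-cell genes had a median of 0.50, with 6 of 14 members higher, among them Col4a2 (1.59), Nid2 and Lama4 (both 1.22). Plvap itself was at 1.33 FPKM against 1.72 FPKM with overlapping intervals. Of 8 mural cell genes 4 were higher (median 0.68): Acta2, Pdgfrb (0.90), Abcc9 (0.89) and Notch3 (0.86). Arterial and venous genes had a median of 0.28, with Gja4 (0.98) and Aplnr (0.96) beside Slc38a5, and 0.05, inside the random range, with a minimum of 5 FPKM. The 5 tested erythroid genes, which include the near-identical Hba-a1 and Hba-a2 and are not independent, had a median of 1.24. Hba-a1 was at 99.8 FPKM against 42.1 FPKM, so globin RNA was higher in the same library as the vascular genes.

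Ganglion cell genes had a median of 0.37, with Nefm (0.74), Pou4f2 (0.66) and Pou4f1 (0.62) above 1.5-fold. Hypoxia genes had a median of -0.21 and 1 of 29, Ak4 (-0.70), was 1.5-fold lower. Cone genes had a median of -0.24, led by the opsin gene Opn1mw, at 6.56 FPKM against 20.1 FPKM (-1.55). Without Opn1mw the cone median of -0.18 lay inside the random range. Astrocyte genes (0.30), amacrine cell genes (0.12) and immediate early genes (0.17) lay above their random ranges, the amacrine list not after the correction for length and GC content (0.09). Norrin/Fz4 pathway components (0.05), Wnt targets (0.07), gliosis (0.14), Muller glia (-0.08), microglia (-0.07), rods (-0.07), bipolar (-0.15) and horizontal cells (-0.08), proliferation (0.17), interferon response (0.07), pigment epithelium (0.16) and the sex-linked genes (0.07) did not stand apart. Some of these did under an alternative, such as microglia with a minimum of 5 FPKM (-0.34) and bipolar cells after the correction (-0.22). Of 9 pigment epithelium genes 3 were 1.5-fold higher, Pmel (0.78), Rpe65 (0.72) and Rgr (0.59), and none was 1.5-fold lower. Axin2 was at 5.35 FPKM in the stabilized library and 5.37 FPKM in WT, and Tcf7 at 1.54 FPKM against 0.707 FPKM. Whole-retina RNA mixes all cell types, so the flat Axin2 values here and in the knockout do not show that endothelial Axin2 was unchanged.

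At 2-fold, 92 genes were higher and 95 lower, of which 55 and 80 were short RNA genes. Of the 37 other higher genes 36 had intervals apart from those of WT, against 9 of the 15 lower ones. Unchanged pairs gave 47.3 higher and 49.2 lower calls outside short RNA genes, so these totals do not exceed those of unchanged pairs either. The observed 15 lower calls lay below the lowest draw of 30, so here too the draws were noisier than the libraries and cannot judge the totals. Calls with intervals apart in unchanged pairs numbered 0.8 higher and 2.2 lower on average. That reference was chosen after the totals had been seen, and uses the same intervals for the draws and for the call. The genes of lowest ratio with a value in both libraries included the dopamine receptor gene Drd4 (-1.56), Opn1mw and Gdf1 (-1.42), the last with wide, overlapping intervals. The ribosomal protein genes Rps27 (-2.52) and Rpl26 (-1.99) have many near-identical copies and are uncertain.

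The stabilized knockout against the knockout addresses the same activation in the absence of Ndp. Cldn5 was at 16.7 FPKM (13.5 to 20.0) against 0.675 FPKM (0.378 to 0.971), 24.8 times as high by the deposited values and a log2 ratio of 3.87. Slco1c1 (2.44), Mfsd2a (2.36) and Pglyrp1 (2.24) were higher too, and Abcb1a was at 1.02 FPKM against 0.0665 FPKM. Plvap was lower, at 2.22 FPKM (1.58 to 2.87) against 4.40 FPKM (3.30 to 5.50), a log2 ratio of -0.85. Acta2 was at 3.38 FPKM against 0.756 FPKM (1.63).

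Of 16 pan-endothelial genes 10 were 1.5-fold higher (median 0.77, random range -0.07 to 0.16), led by Tie1 (1.55), Sox18 (1.23), Cd34 (1.15) and Eng (1.12). Barrier genes had a median of 0.51 with 8 of 16 members higher. Fenestrated and tip-cell genes had a median of 0.48 with 6 members higher and 2 lower, Plvap and Adm (-0.81). Mural cell genes had a median of 0.67, with Rgs5 (1.13) and Abcc9 (0.90) after Acta2. With a minimum of 5 FPKM that median was 0.02, inside the random range, on fewer members. Arterial and venous genes had a median of 0.12, inside the random range, with Slc38a5 (1.45), Aplnr (1.29) and Gja4 (1.06) above 1.5-fold. Erythroid genes had a median of 1.19, and Hba-a1 was at 119 FPKM against 51.5 FPKM. Gliosis genes had a median of 0.30 with no member beyond 1.5-fold, and microglia genes 0.23, or 0.11 inside the random range with a minimum of 5 FPKM. Hypoxia genes had a median of -0.12 with Adm lowest. Vegfa was at 90.8 FPKM against 116 FPKM.

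Rods (-0.09, with Gnat1 at -0.91), bipolar cells (-0.11), Muller glia (-0.07) and pigment epithelium (-0.12) lay below their random ranges, Muller glia not without the largest member (-0.04) and pigment epithelium not without a filter (0.01). Astrocytes (0.25, or 0.17 inside the range without the largest member), amacrine cells (0.15), ganglion cells (0.15) and proliferation (0.31) lay above theirs. Pathway components (0.06), Wnt targets (0.14, with Apcdd1 at 0.80 and Tcf7 at 0.71), cones (-0.01), horizontal cells (-0.02), interferon response (0.17), immediate early genes (0.05) and sex-linked genes (0.02) lay inside. At 2-fold 104 genes were higher and 61 lower, and 57 and 11 outside short RNA genes. Of these, 51 and 7 had intervals apart. Unchanged pairs gave 49.8 and 50.1 calls outside short RNA genes, up to 62 higher in a single draw, and 3.3 and 2.3 with intervals apart. No draw gave fewer than 28 lower calls outside short RNA genes, so these draws too were noisier than the libraries. Apobec3, which encodes a cytidine deaminase that restricts retroviruses, was among the highest at 9.68 FPKM against 0.515 FPKM (3.33). Cbx7, between Apobec3 and Pdgfb, was at 18.8 FPKM against 8.76 FPKM (1.06). Amd1, Rps27 and Klk1b22 belong to groups of near-identical copies and are uncertain.

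**Figure D2:**
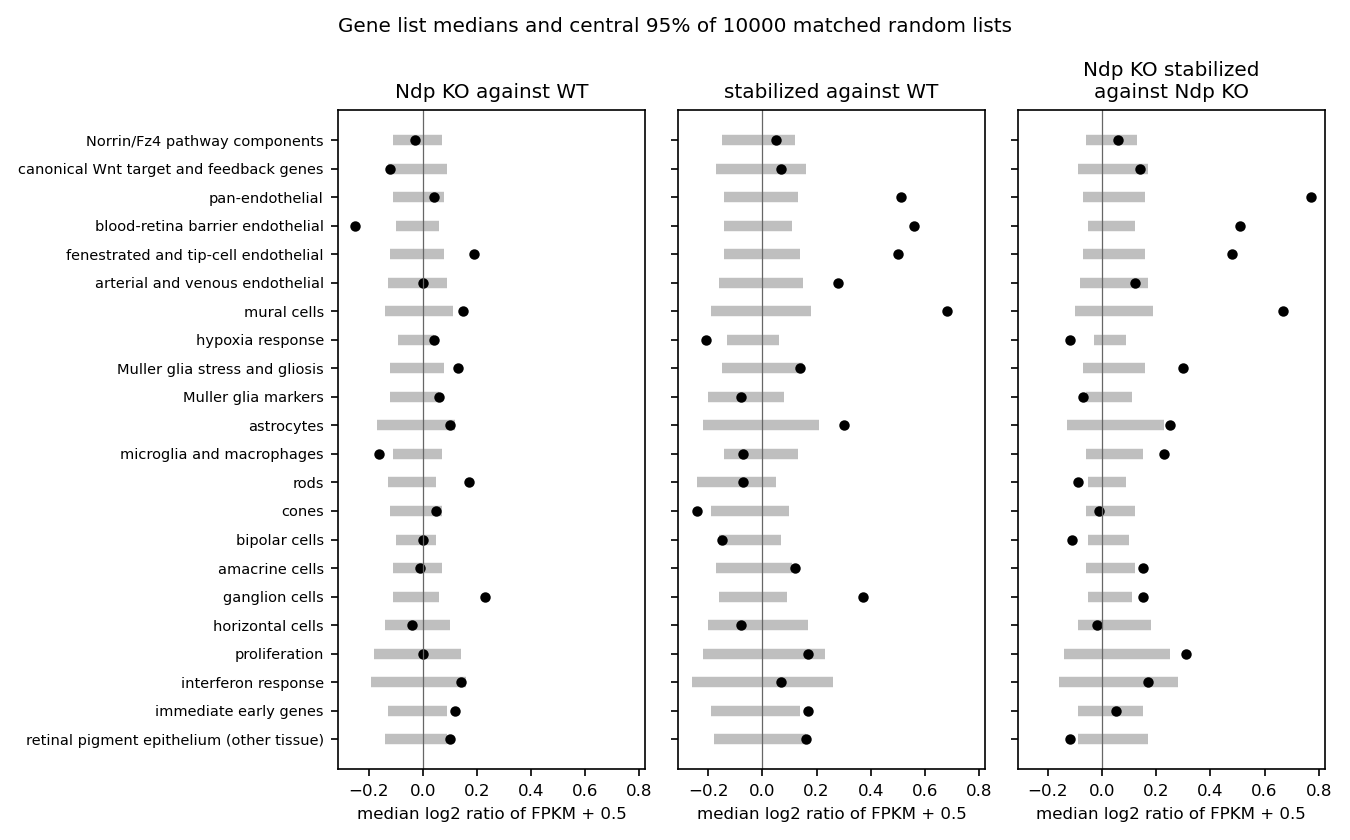
Median log2 ratio of FPKM + 0.5 (horizontal axis) of 22 gene lists in 3 contrasts; points are list medians and grey bars the central 95% of 10000 random lists matched on expression, with the erythroid and sex-linked lists left out. The pan-endothelial median is 0.04, 0.51 and 0.77 from left to right, and the barrier median -0.25, 0.56 and 0.51.

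The contrasts of stabilization with and without Ndp share no library. Outside short RNA genes, 23 genes were 2-fold higher in both and 4 lower in both. Independent lists of those sizes would share 0.16 and 0.01, but noisy genes recur, and unchanged libraries drawn from the deposited intervals shared 9.9 higher calls on average (4 to 17 in 100 draws) and 10.8 lower calls (1 to 20). The shared higher genes exceed that range and the shared lower genes do not. Those draws were noisier than the libraries, so the comparison of the lower genes decides nothing. All 23 higher genes had intervals apart in both contrasts, against 0.07 in unchanged draws, and 2 of the lower genes did, against 0.63 on average and at most 2. The shared higher genes were Acta2, Apobec3, Cd93, Cldn5, Col4a1, Eltd1, Eng, Gdpd3, Hba-a1, Hba-a2, Klhl33, Lama4, Mfsd2a, Nid1, Pglyrp1, Prnd, Serpina3h, Slc38a5, Slco1c1, Sox18, Tie1, Txnip and Vwa1. The shared lower genes were Drd4 and Gm14440, with intervals apart, and Gdf1 and LOC100861572, with overlapping intervals. The correlation of log2 ratios across genes, which are not independent replicates, was 0.50 without short RNA genes and 0.15 with them. The contrasts of Ndp genotype, knockout against WT and stabilized knockout against stabilized, also share no library. Their correlation was 0.28 without short RNA genes and 0.07 when genes on X and Y were left out too. The 4 shared higher genes were Y-linked, and the shared lower ones included Ndp and Xist, and Bc1 and Hist2h2aa2 with overlapping intervals. Unchanged draws shared 3 to 18 higher and 4 to 19 lower calls, ranges that hold the observed counts. These draws were noisier than the libraries, so that does not decide whether the shared calls exceed noise. With intervals apart in both contrasts 4 higher and 3 lower genes were shared, against at most 1 and 0 in unchanged draws.

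**Figure D3:**
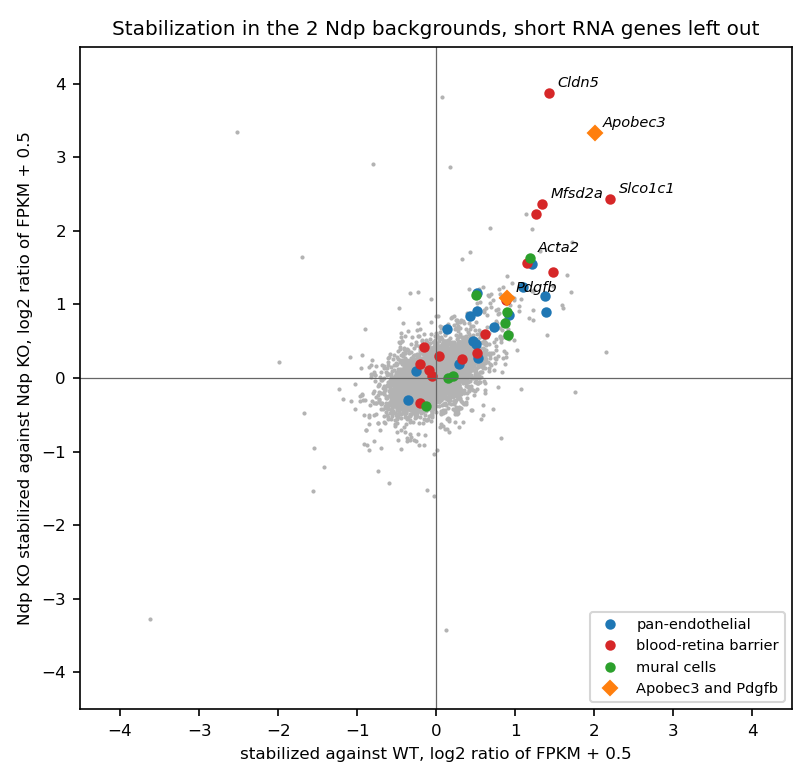
Log2 ratio of FPKM + 0.5 for each gene in the stabilized library against WT (horizontal axis) and in the stabilized knockout against the knockout (vertical axis); grey points are 12896 genes without short RNA genes, colours mark 3 fixed lists and a pair of genes, and 5 genes lie outside the axes. Cldn5 lies at 1.43 and 3.87 and Apobec3 at 2.01 and 3.33.

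The stabilized knockout against WT measures the distance that remained to WT. Cldn5 was 2.42 times the WT value (log2 ratio 1.22), Mfsd2a 4.05 times (1.66) and Slco1c1 5.85 times (1.65), so these barrier genes were above and not at the WT level. Plvap was at 2.22 FPKM against 1.72 FPKM with overlapping intervals. Col4a1 (1.80) and Acta2 (2.12) were higher, and Ndp was lower (-1.35).

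List medians in this contrast were 0.70 for pan-endothelial genes (9 of 16 members higher), 0.48 for barrier genes (7 of 16), 0.59 for fenestrated and tip-cell genes (7 of 14) and 0.60 for mural cell genes (4 of 8). The barrier median was 0.10, inside the random range, with a minimum of 5 FPKM. Erythroid genes had a median of 1.48. Gliosis genes had a median of 0.31, with Gfap (1.04) and A2m (1.03) highest, and astrocyte and ganglion cell genes had medians of 0.48 and 0.41. Hypoxia (-0.09), cone (-0.12) and pigment epithelium (-0.20) genes lay below their random ranges. The hypoxia median of -0.08 with a minimum of 5 FPKM, the cone median of -0.11 without the largest member and the pigment epithelium median of -0.09 with other filters lay inside. At 2-fold, 98 genes were higher and 84 lower, and 57 and 15 outside short RNA genes. Of these, 54 and 11 had intervals apart.

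The stabilized knockout against the stabilized library tests the loss of Ndp where beta-catenin is stabilized. The pan-endothelial (0.08), barrier (0.02), fenestrated and tip-cell (0.09), mural (0.04) and erythroid (0.07) medians all lay inside their random ranges. Slc38a5 was lower (-0.76), Pglyrp1 (0.64) and Acta2 (0.94) were higher, and Cldn5 was at 16.7 FPKM against 19.4 FPKM with overlapping intervals. Pigment epithelium genes had a median of -0.35, led by Rpe65 (-0.92), while gliosis (0.26), astrocyte (0.33), microglia (0.17), Muller glia (0.14) and hypoxia (0.11) genes lay above their random ranges. With a minimum of 5 FPKM the gliosis median was 0.02, inside the range, and the mural median 0.21, above it. At 2-fold 76 genes were higher and 56 lower, and 19 and 10 outside short RNA genes, of which 15 and 6 had intervals apart. The Y-linked genes, Xist and Ndp (-1.06) were among them.

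The difference between the stabilization contrasts without and with Ndp was 2.45 for Cldn5, 1.02 for Mfsd2a and -0.57 for Plvap on the log2 scale. The barrier list had a median difference of 0.22, above its random range of -0.05 to 0.16, and the pan-endothelial list 0.05, inside it. Microglia (0.40) also lay above its range. The 7 lists below theirs were fenestrated and tip-cell (-0.17), mural (-0.12), rods (-0.06), ganglion cells (-0.18), interferon response (-0.19), immediate early genes (-0.20) and pigment epithelium (-0.44). These differences were not tested, since they leave no residual degree of freedom with 1 library per group.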

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

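All tests in this part except that of the neighbours of Pdgfb within 200 kb were chosen after the results were seen. The levels of 1 of those neighbours, Nptxr, which overlaps Npcd, had been seen before that test as well. The bounds for the tests of vessel number, sex and endothelial cell number were rewritten after their first values were known. The test of endothelial cell number was first run on the 4 barrier genes picked as low in the knockout, where the gap was 0.79, and was then changed to the whole barrier list, because that gap is partly built in by the choice of genes. No difference between the backgrounds named in the next paragraph was tested, because each rests on single libraries.

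A few genes had ratios of opposite sign in the backgrounds compared. Klk1b22 differed by -0.80 with stabilization when Ndp was intact and by 2.92 when it was absent. The same gene differed by -0.77 with loss of Ndp in unmodified and by 2.94 in stabilized retinas. Rps27 differed by -2.52 and 3.34 in the stabilization contrasts and by -2.67 and 3.19 in the Ndp contrasts. LOC100302567 differed by 1.46 and -5.60 in the Ndp contrasts, and is listed at 0 in the stabilized knockout, so the second value depends on the pseudocount. Klk1b22 and Rps27 have near-identical copies, and the interval of Rps27 in WT spans 0 to 126 FPKM.

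The vascular lists were higher in both libraries with stabilized beta-catenin. After removal of the trend on transcript length and GC content the pan-endothelial medians were 0.53 and 0.77, against 0.51 and 0.77 before, which argues against that trend as the cause. A lower share of photoreceptor RNA would raise other cell types alike, but the pan-endothelial median exceeded the median of 5 other cell type lists by 0.58 and 0.62. More numerous or larger vessels and more RNA per endothelial cell cannot be told apart, since 6 of 16 pan-endothelial genes were 1.5-fold higher in both contrasts and whole-retina RNA holds no count of cells. An effect of stabilized beta-catenin, which the design names, stays open as a hypothesis, as does any effect of CreER itself, since both libraries carry both.

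Pdgfb and Apobec3 were higher in both libraries with CreER. Extra copies of a region reaching 200 kb to each side of Pdgfb are argued against, because the median ratio of 8 other tested neighbours was 0.03 in the stabilized library against WT and 0.11 in the stabilized knockout against the knockout. That window can hide a shorter segment: Cbx7, the 1 tested gene between Apobec3 and Pdgfb, had ratios of 0.72 and 1.06, and Apobec3, Cbx7 and Pdgfb were the only run of 3 adjacent tested genes with a reference position, short RNA genes left out, that was 1.5-fold higher in both contrasts, with 0 other runs. Extra copies of a segment from Apobec3 to Pdgfb carried with the transgene may therefore be a candidate explanation, found and tested on the same data. The 3 genes did not rise alike, with ratios of 2.01 and 3.33 for Apobec3 and 0.90 and 1.09 for Pdgfb, and no copy number was measured. The higher Pdgfb alone is also consistent with the vascular lists, since 5 and 4 pan-endothelial genes had higher ratios in these contrasts, so Pdgfb does not decide between these explanations.

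Barrier genes were lower in the Ndp knockout. Sex cannot be told apart from the Ndp genotype, because both knockout pools are male and both others female. The median of the 4 barrier genes low in the knockout was -0.38 (SD 0.47) in the stabilized knockout against the stabilized library, which is again a contrast of both. Of the 4, Slc38a5 is X-linked and had -0.73 in the knockout against WT and -0.76 in that contrast. The others had -0.21 (Cldn5), -0.55 (Slco1c1) and 0.32 (Mfsd2a) in that contrast. Fewer endothelial cells in the knockout cannot be told apart from lower RNA of these genes per cell either, because the pan-endothelial median lay 0.29 above that of the whole barrier list, close to the SD of 0.27 among pan-endothelial genes. Cldn5 (-2.66) lay far below the lowest of those (-0.45), but it is a single gene. Slco1c1 (-0.78), Slc38a5 (-0.73) and Mfsd2a (-0.70) lay below it by less, and the other 12 tested barrier genes were within 1.5-fold. Barrier genes below the minimum mean, among them Abcb1a, were not counted. The 4 genes beyond 1.5-fold were picked as low, so their place below that range is partly built in and does not decide the question.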

How the results depend on the processing

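The alternatives without short RNA genes, without X and Y genes and corrected for transcript length and GC content were chosen after seeing the data. The labels give no replicate numbers to pair libraries by. A fit over both stabilization contrasts matched by Ndp state was not run, and these were compared by shared calls and correlation only. Leaving out replicates does not apply with 1 library per group.

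Counts are given as higher then lower, for the knockout against WT, the stabilized library against WT, the stabilized knockout against the knockout, against WT and against the stabilized library. At 2-fold they were 59 and 106, 92 and 95, 104 and 61, 98 and 84, and 76 and 56. Without short RNA genes they were 11 and 20, 37 and 15, 57 and 11, 57 and 15, and 19 and 10, since most calls are short RNA genes. Corrected for length and GC content, which also leaves those genes out, they were 7 and 17, 33 and 12, 53 and 6, 45 and 8, and 18 and 8. With intervals that do not overlap they were 9 and 15, 36 and 9, 51 and 7, 54 and 12, and 15 and 8. At 1.5-fold they were 127 and 160, 220 and 225, 231 and 121, 236 and 141, and 129 and 91. With a minimum of 5 FPKM the higher counts of the stabilized knockout were 58 against the knockout and 59 against WT, from fewer genes. The other 88 of 130 counts stayed within 1.5 times.

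The correlation of the Ndp contrasts moved from 0.11 to 0.28 without short RNA genes and 0.38 with the correction, and that of the stabilization contrasts from 0.15 to 0.50 and 0.51. The other 18 values moved by less than 0.1.

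Of 240 medians of the pan-endothelial, barrier, fenestrated and mural lists under alternatives, 233 kept their call. With a minimum of 5 FPKM the barrier median was -0.05 in the stabilized library against WT and 0.10 in the stabilized knockout against WT, and the mural median 0.02 in the stabilized knockout against the knockout, on fewer members. The mural median in the knockout against WT was 0.02 with a minimum of 0.5 FPKM, 0.01 with no filter and 0.09 with the correction; the cause was not tested. The correction says nothing of the erythroid list, where 2 of 5 members have a length. The mural median of the stabilized knockout against the stabilized library reached 0.21 with a minimum of 5 FPKM. Of 1458 medians of other lists and differences 34 lost and 43 gained a call. Of 972 values of named genes 21 lost and 5 gained the 1.5-fold size. No call reversed. Values below about 1 FPKM are limited by depth, most in the stabilized library at 0.426 of the depth of WT.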

Other observations

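No tests were run in this part, and Nid1, Spp1 and Slc39a8 were chosen after their values were seen. The vascular genes shared by both stabilization contrasts went with genes outside the lists and with Opn1mw of the cone list. Nid1, which encodes a basement membrane protein, was at 4.40 and 3.83 FPKM in the stabilized libraries and 1.05 and 1.13 FPKM in WT and knockout. The dopamine receptor gene Drd4, expressed in photoreceptors, had log2 ratios of -1.56 and -1.54 with stabilization in the presence and absence of Ndp, and of 0.83 in the knockout against WT. Opn1mw was at 20.1 and 18.3 FPKM without and 6.56 and 9.22 FPKM with stabilization. Spp1, the osteopontin gene, was at 1.28 FPKM in the knockout and 4.77 to 7.94 FPKM in the other libraries, and Slc39a8, a metal ion transporter gene, at 0.174 FPKM in the knockout and 0.977 to 1.56 FPKM elsewhere.

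The median ratios of the tenth of genes with the lowest GC content and the tenth with the highest were -0.15 and 0.09 in the stabilized library against WT, and -0.02 and 0.06 in the stabilized knockout against the knockout.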
